A study of Drosophila melanogaster with 2 samples.

How the data were processed

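Anti-GFP ChIP-seq was done on whole pupae of a transgenic fly line with a C-terminal GFP fusion of CG9948, with chromatin fragmented by sonication, per the labels. Both samples were put in 1 group from the labels' strain, stage and age (24 h), and they are separate biological replicates per the labels. The replicate numbers 1 and 3 are those of the labels.

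The 4 deposited peak lists are in narrowPeak format on assembly dm6, per the deposited readme texts. Those texts say that each replicate list was derived from the replicate's alignments and a control, the pooled list from both alignments and the control, and the optimal IDR (irreproducible discovery rate) list from both replicate lists and the pooled list. The aligner, the peak caller and their versions and thresholds are not given in the sources used here, and the control was not analysed here. The signal of each peak is the authors' own value on an unstated scale, and it was used to describe, rank and filter peaks within one list and, across shared peaks, to correlate both replicates. The deposited −log10 q-value was not used for any test, since all 7637 IDR peaks hold the maximum of its list (4.24). The third value used is the deposited summit position, given as an offset from the peak start. It equalled the peak width in 2, 10, 7 and 3 peaks of the lists of replicate 1, replicate 3, the pooled reads and IDR, where the last base of the peak was taken. All 3 lists of 30000 peaks have the same length, so their length does not measure enrichment. Overlapping peaks merge into 28485, 25358, 26065 and 7453 regions in the same order. Read depth cannot be read from the lists, and intervals cover counting error over peaks or genes only.

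Gene positions came from Ensembl release 115 (BDGP6.54) and sequence from the RefSeq release 6 genome, both in dm6 coordinates, and coordinates are given 1-based. Chromosomes 2L, 2R, 3L, 3R, X and 4 were used, with 13945 protein-coding genes and 23136 distinct TSSs, and transposable element genes were left out. Each summit was put in the first class that applied: promoter (within 500 bp of a TSS), 5′ UTR, coding exon, 3′ UTR, noncoding exon, intron and intergenic DNA. Placement and overlap were tested with 100000 circular shifts, in which all peaks of a chromosome move by a common random distance. Genes were compared with Fisher's exact test, summit sides with an exact binomial test, and motifs and 7-mers with an exact McNemar test of the window within 50 bp of the summit against flanks of equal total length centred 200 bp away. Log2 ratios of motif counts have 0.5 added to both counts. The CACTG core was compared between groups of peaks also within 2% bins of summit A + T content (Mantel-Haenszel). Benjamini-Hochberg adjustment was applied over the 7 classes, the 35 lists, the 23 motifs and the 8192 7-mers, with a threshold of 0.05. Shares have 95% Wilson intervals, and the median distance a bootstrap interval from 2000 draws. Peaks and genes near each other are not independent, so p-values of the tests on genes and sequences are too small by an unknown amount. Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3, Numba 0.67.0, NetworkX 3.6.1 and matplotlib 3.10.9 were used.

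The tests, the gene lists, the motifs, the rule for named genes and all alternatives but those listed at the end were fixed before the data were examined. Named are CG9948, the 25 protein-coding genes with the strongest promoter peaks that overlap a peak in both replicate lists, up to 4 members with the strongest peaks and up to 2 without one in each list that passed, up to 2 members in other lists, and the 10 strongest peaks outside promoters. A rule to name the 10 7-mers with the smallest p was also fixed, but these sequences are not used here, and 7-mers are given as counts. Each of the 25 strongest promoter peaks and of the 10 peaks outside promoters was given to the gene with the nearest TSS. In the tests and for the named list members, a gene had a promoter peak when any of its TSSs lay within the window of a summit. Neighbours can therefore share one, and a peak named for a list member can lie nearer to another gene. The 35 lists cover ribosomal, proteasome, translation, splicing and respiratory chain proteins, cuticle, receptor, histone, autophagy and heat shock genes, immune peptides, ecdysone, patterning and signalling genes, chromatin and insulator proteins, cell cycle, tissue, clock, piRNA and testis genes, and 4 classes of small RNA genes. For 11 listed symbols the annotation's current symbol was used.

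A choice in the list test was changed after its results had been seen. At first a noncoding list was compared with all annotated noncoding genes, and these include mature microRNA entries, which have no TSS and so can never have a promoter peak. They were then left out, which lowered the lists that passed from 9 to 7. The microRNA list went from 12 of 741 genes (adjusted p = 2.17e-13) to 12 of 260 (0.0607), and the ecdysone response list, with the same 8 of 19 genes, from an adjusted p of 0.0493 to 0.0554 (Fisher's exact tests). The first version is kept among the alternatives.

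Tried on simulated data were the promoter share, overlap count, list, 7-mer and motif tests, composition matching and the stratified odds ratio, and no others. Of 20 sets of uniformly random positions, which lack the clustering of peaks, 1 gave p under 0.05 for the promoter share (permutation test). With part of the positions planted at TSSs, a promoter share of 30.8% was expected and 30.8% was found. The expected value used the shifted share from the test itself. A planted replicate overlap of 59.3% was found as 59.9%. Of 100 random gene lists 0 were called, and a planted list had an adjusted p of 4.43e-10 (Fisher's exact test). These lists and the genes with peaks were drawn at random, so false calls among clustered genes that share peaks were not tested. In windows with no planted sequence 0 of 8192 7-mers were called, and a 7-mer planted in 5% of windows ranked 1. These windows lay at random positions, so false calls at summits that differ from their flanks in A + T content were not tested. Windows matched to random positions had a promoter share of 13.4% where the genome has 13.5%. A simulated odds ratio of 2 with a crude value of 2.93 came out as 1.99 after stratification.

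Alternatives were promoter windows of 250 and 1000 bp, protein-coding TSSs only, other overlap rules (1 bp, or summits within 100 bp), the strongest 3818 IDR peaks, the 7637 strongest peaks of either replicate alone, 1 gene per divergent pair, 1 gene per promoter peak on the 5 large arms, flanks centred 400 bp away, dinucleotide-shuffled windows, and promoter and other peaks apart. Added after seeing the data were 1 summit per group of overlapping peaks, shuffled windows for 7-mers, the A + T content of summits, the first noncoding gene set, and composition-matched windows. The last are random genomic windows in the same 2% bin of summit and 4% bin of flank A + T content, at least 1 kb from any pooled peak when motifs were compared.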

Results

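Chromatin bound by CG9948 was profiled by ChIP-seq in whole Drosophila melanogaster pupae aged 24 h. CG9948 is an uncharacterized fly gene, and the flies carried a transgene coding for the protein with GFP at its C terminus, which was precipitated with an antibody against GFP. The 2 samples form a single group and are biological replicates, numbered 1 and 3 in the labels, so the data allow no comparison between conditions. They answer where in the genome the tagged protein was enriched, how well both replicates match, and which genes and sequences lie at the peaks. The deposited lists hold 30000 peaks for replicate 1, 30000 for replicate 3, 30000 for the pooled reads and 7637 in the optimal IDR set, called IDR peaks below. The IDR peaks cover 2.28 Mb, 1.70% of chromosomes 2L, 2R, 3L, 3R, X and 4 of assembly dm6. Read depth is unknown, because the lists give no read counts.

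The strongest IDR peaks lay at the same places in both replicates. The peak at the CG14100 promoter had the highest signal of the IDR peaks (5871) and signals of 2396 and 3486 in replicates 1 and 3. Of the 7637 IDR peaks, 6958 (91.1%, 95% Wilson interval 90.4 to 91.7) overlapped a peak in both replicate lists by at least 50% of the shorter peak. Another 227 overlapped a peak of replicate 1 only, 448 a peak of replicate 3 only, and 4 a peak of neither. Peaks moved together by a random distance along each chromosome overlapped both lists in 3.25% of cases on average and 19.7% at most (one-sided permutation test, p = 1e-05, the smallest that 100000 shifts can give). Since the IDR set was itself derived from both replicate lists, part of this overlap follows from its selection. Among the 7637 strongest peaks of each replicate, chosen without IDR, 76.7% (75.7 to 77.6) of those of replicate 1 were found in replicate 3 and 78.0% (77.0 to 78.9) of those of replicate 3 in replicate 1. Shifted peaks gave 2.04% on average (permutation p = 1e-05). Across the 6958 shared peaks, signals of both replicates had a Spearman correlation of 0.826 and a Pearson correlation of log2 signal of 0.845, and 0.845 also without the 2 peaks farthest from the median. Since IDR selects peaks of similar rank in both replicates, these values depend on that selection. Across the 13651 of 30000 pooled peaks found in both replicate lists, taken without IDR, they were 0.842 and 0.876, a comparison added after the data were seen. All these correlations run across peaks, which are not independent replicates.

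Among promoter peaks of protein-coding genes, the strongest lay at genes with varied functions. After CG14100, with its summit 89 bp upstream of the transcription start site (TSS) at 3L:19590613, came Ugalt, a UDP-galactose transporter gene (signal 4986, X:2703887), mRpL41, which codes for a mitochondrial ribosomal protein (4407, 2R:15217753), Chro, which codes for a chromodomain protein of interbands (3924, 3L:22878902), and the small heat shock gene Hsp27 (3756, 3L:9383906). By signal among all IDR peaks, CG14100 ranked 1 and Ugalt 3, and the peak between them is not among those named here. The summits at Ugalt, mRpL41 and Hsp27 lay 35, 136 and 157 bp upstream of a TSS, and that at Chro 82 bp downstream. The next were larp (3721), PNPase (3637), Tcs5 (3618), Art3 (3600) and CG18549 (3568). The remaining 15 of the 25 strongest promoter peaks had signals from 3418 at CG18428 down to 2599 at the stress kinase gene p38a. They included CG5611, CenG1A, Fkbp14, CG13921, Pal1, Tina-1, CG8320, C1GalTA, cu, CG13390, CG5098, CG3552 and the Polycomb group gene ph-p (2846, X:2137334). All 25 overlapped a peak in both replicate lists, as the rule that named them required.

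Promoters held 2280 of the 7637 IDR summits, or 29.9% (28.8 to 30.9), against 13.5% of shifted summits, a 2.21-fold excess (one-sided permutation test, p = 1e-05, the smallest possible). A promoter was any base within 500 bp of an annotated TSS. Coding exons were almost empty of summits: 5 of 7637 (0.0655%, 0.0280 to 0.153) against 13.7% of shifted summits, a 209-fold deficit. These 5 summits, named after their values were seen because they are so few, lay in otp, Pvf3, sgg, Snx27 and CG1632, with signals of 279, 190, 181, 169 and 152. The count depends on the window and the replicate: 11 with a 250 bp promoter window, 2 with 1000 bp, 6 without replicate 1 and 15 without replicate 3, each of 7637, against 10.4% to 15.5% of shifted summits. Summits were also scarce in 3′ UTRs (0.537% against 4.43%), 5′ UTRs (0.406% against 0.779%) and intergenic DNA (21.3% against 27.4%). Introns held 46.7% against 39.4%, and exons of noncoding genes 1.13% against 0.814%. Shifted summits can fall in repeated DNA to which reads may not be placed uniquely, and read placement was not measured. How far it contributes to these differences, the promoter excess included, was not tested. The adjusted p over the 7 classes was 3.5e-05 for promoters, coding exons, 3′ UTRs and introns, 5.6e-05 for intergenic DNA, 0.000233 for 5′ UTRs and 0.0168 for noncoding exons (two-sided permutation tests). The noncoding exon difference did not pass with a 1000 bp promoter window (adjusted p = 0.367), in the strongest 3818 peaks (0.0797) or without replicate 1 (0.0589), with a range of 0.00578 to 0.367 over the 6 alternatives (all permutation tests).

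**Figure D1:**
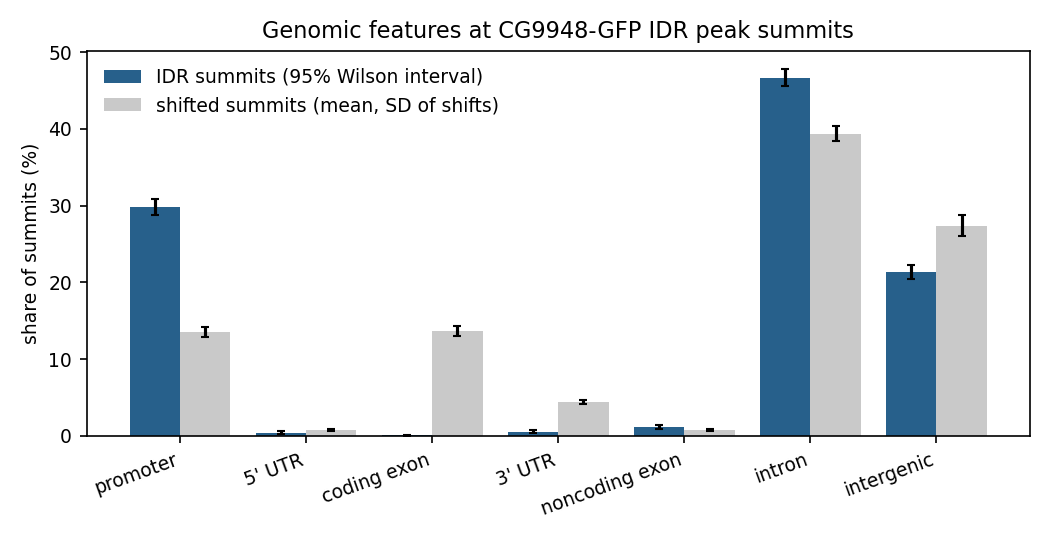
Share of IDR peak summits (blue, with the 95% Wilson interval) and of shifted summits (grey, mean and SD of 100000 shifts) in 7 feature classes, in percent. Promoters held 29.9% of IDR summits against 13.5% of shifted ones, and coding exons 0.0655% against 13.7%.

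Several of the strongest peaks lay outside promoters. The strongest was at 2L:481088 in an intron of ush, which codes for a zinc finger cofactor of GATA factors, 1.40 kb upstream of a TSS of cbt (signal 4697, replicates 1671 and 3028). Others lay in introns of CG11050 (4033), CG32772 (3695), the GAGA factor gene Trl (3268) and the kinase gene Lk6 (3110), and in an intron shared by HmgD and HmgZ (3735). A peak 13.9 kb downstream of the nearest osa TSS (3375) and one 6.06 kb downstream of the nearest CG4004 TSS (3258) lay in exons of noncoding genes. The intergenic peaks nearest to CG31668 (3592) and CG13323 (3215) were 3.75 and 11.9 kb from a TSS.

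Promoter peaks were more common among strong peaks. Of the IDR peaks divided into 5 groups by signal, the strongest had 583 of 1527 summits in promoters (38.2%, 35.8 to 40.6), and the weakest 407 of 1529 (26.6%, 24.5 to 28.9; odds ratio 1.70, 1.46 to 1.99, two-sided Fisher's exact test, p = 9.38e-12). The 3 groups between them had 28.3%, 28.7% and 27.5%.

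Summits at promoters of protein-coding genes lay mostly upstream of the TSS. Of 2060 summits within 500 bp of such a TSS, 1687 were upstream, 371 downstream and 2 at the TSS (82.0% upstream of those not at the TSS, 80.3 to 83.6, exact binomial test, two-sided, p = 8.67e-200). The median summit was 147 bp upstream (bootstrap 95% interval 140 to 153).

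**Figure D2:**
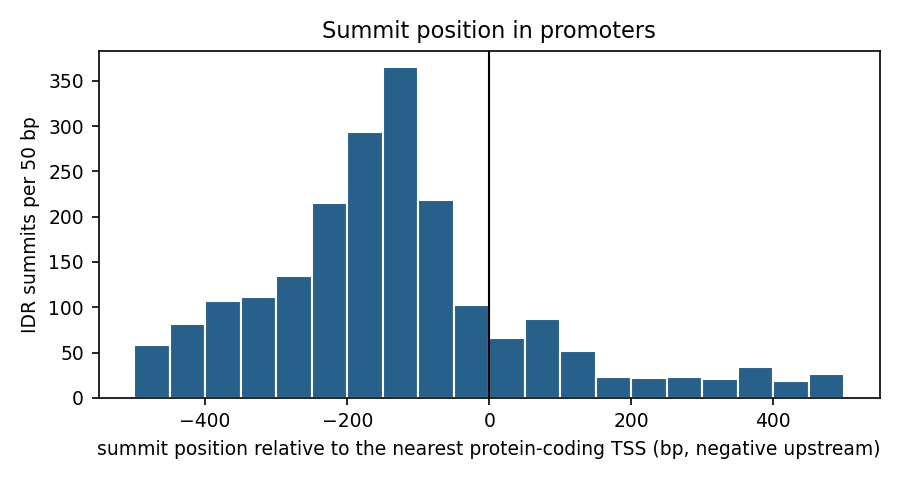
Number of IDR summits per 50 bp by position relative to the nearest protein-coding TSS, in bp, with negative positions upstream. Of the 2060 summits shown, 1687 lie upstream, with a median 147 bp upstream.

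Genes with a divergent neighbour had promoter peaks more often. Of 5052 protein-coding genes with a TSS within 1 kb of that of a divergently transcribed gene, 1550 (30.7%, 29.4 to 32.0) had a promoter peak, against 965 of 8893 other genes (10.9%, 10.2 to 11.5; odds ratio 3.64, 3.32 to 3.98, two-sided Fisher's exact test, p = 2.26e-181). Members of a pair can share a peak. Counting 1 gene per group of divergent genes, 752 of 2412 (31.2%) had a peak. A gene so counted can still have its peak through the promoter of its neighbour.

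Genes on the X and on the autosomes did not differ detectably. Of 2196 protein-coding genes on the X, 416 (18.9%, 17.4 to 20.6) had a promoter peak, against 2090 of 11669 (17.9%, 17.2 to 18.6) on 2L, 2R, 3L and 3R (odds ratio 1.07, 0.951 to 1.21, two-sided Fisher's exact test, p = 0.251). The direction was not stable: the odds ratio was 0.937 with a 250 bp window, 0.946 in the strongest 3818 peaks and 0.963 without replicate 1, while it passed the threshold at 1.14 with a 1000 bp window (p = 0.0180) and 1.17 without replicate 3 (p = 0.0104, both Fisher's exact tests). Chromosome 4 had 13 IDR peaks, or 9.64 per Mb against 57.0 over all chromosomes, and 9 of its 80 protein-coding genes had a promoter peak. Its count differed between the replicates, with 7 of the 30000 peaks of replicate 1 and 196 of the 30000 of replicate 3, and 4 and 17 of their 7637 strongest.

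Among 35 gene lists, 7 differed from other genes of their kind. Above the others were the cytosolic ribosomal protein genes, of which 43 of 93 had a promoter peak (46.2%, 36.5 to 56.3, against 17.8%; odds ratio 3.96, adjusted p = 6.14e-09), the Hippo growth control pathway with 7 of 12 (58.3%, 32.0 to 80.7; odds ratio 6.38, adjusted p = 0.0122) and the insulator and architectural proteins with 8 of 18 (44.4%, 24.6 to 66.3; odds ratio 3.64, adjusted p = 0.0434, all two-sided Fisher's exact tests). The ribosomal protein genes with the strongest promoter peaks were RpL34b (signal 660), RpL32 (547), RpS27 (435) and RpS20 (371), while RpL10 and RpL10Aa had none. In the Hippo list they were the atypical cadherin gene ft (1602), the myosin gene dachs (860), Mer (554) and yki, the coactivator of the pathway (497), while ds and fj had none. Signals in replicates 1 and 3 were 91.5 and 762 at dachs, so its peak was weak in replicate 1. They were 605 and 1002 at ft, 192 and 362 at Mer, and 219 and 283 at yki. Among insulator proteins the strongest peaks were at Chro (3924), Cp190 (1804), M1BP (765) and BEAF-32 (320), while Elba1 and Elba2 had none. Below the others were the chemosensory receptors (2 of 179, 1.12%, odds ratio 0.0506, adjusted p = 1.57e-11), the histones (2 of 115, 1.74%, odds ratio 0.0797, adjusted p = 7.32e-07), the cuticular proteins (3 of 121, 2.48%, odds ratio 0.114, adjusted p = 1.45e-06) and the snoRNA genes (7 of 269, 2.60% against 9.08% of other noncoding genes, odds ratio 0.268, adjusted p = 0.000437, all Fisher's exact tests). For snoRNA and other small RNA genes the annotated 5′ end stood in for the TSS. Whether a promoter lies there was not tested, so the snoRNA value does not show that their promoters lack peaks. The receptors with a peak were Gr77a (319) and Or67a (158), and Gr10a and Gr10b were among those without. The cuticular genes with a peak were Cpr72Ea (506), Cpr12A (223) and Cpr97Ea (177), with none at Acp65Aa and Ccp84Aa. The histone genes with a peak, His3.3B (586) and His2Av (226), code for replication-independent variants. Most of that list, including His1:CG31617 and His1:CG33801, lies in a repeated cluster to which reads may not be placed uniquely. Read placement was not measured here, so the low histone share cannot be told apart from a lack of placed reads. The snoRNA genes with the strongest peaks were snoRNA:Psi28S-2949 (312), snoRNA:U49:66Da (309), snoRNA:Me28S-A774b (212) and snoRNA:Me18S-G1358c (195), with none at scaRNA:MeU1:95C-A24 and scaRNA:MeU1b-A234. Of the snoRNA genes named with a peak, only snoRNA:Me28S-A774b has one in both replicate lists, and the BEAF-32 peak has one in replicate 3 alone. The receptor, histone and cuticular protein lists passed in all 7 alternatives, with odds ratios of 0.0289 to 0.0808, 0.0565 to 0.0916 and 0 to 0.252. The receptor value was 0.0289 without replicate 3, the cuticular one 0.0733 without replicate 1 and the snoRNA one 0.159 without replicate 3. Among genes of similar A + T contrast near the TSS, the histone odds ratio was 0.141 (0.0332 to 0.597, Mantel-Haenszel). Neither the alternatives nor this value addresses read placement in the histone cluster. The ribosomal protein call was lost without replicate 3 (odds ratio 1.82, adjusted p = 0.0534) and its direction turned in the strongest 3818 peaks (0.393, adjusted p = 0.188; range over the alternatives 2.9e-10 to 0.188, Fisher's exact tests). The Hippo call was lost with a 250 bp window (adjusted p = 0.429, range 0.000735 to 0.429) and the snoRNA call with a 1000 bp window (0.472, range 8.09e-08 to 0.472, all Fisher's exact tests). The insulator call was lost in 4 alternatives, among them that without replicate 3 (odds ratio 1.49, adjusted p = 0.645, range 0.036 to 0.645, Fisher's exact tests).

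The other 28 lists did not pass. The nearest to the threshold were the ecdysone response genes (8 of 19, E23 signal 2214 and Eip75B 891; adjusted p = 0.0554), the microRNA genes (12 of 260, 0.0607), the autophagy genes (8 of 20, 0.0624) and the mitochondrial ribosomal proteins (21 of 73, 0.0689, all Fisher's exact tests). Calls near the threshold depended on the setting. The ecdysone response list passed in 5 of 7 alternatives, with adjusted p from 0.011 with 1 gene per peak to 0.359 with a 250 bp window, and the microRNA list also in 5 (2.17e-13 to 0.264, Fisher's exact tests). Without replicate 1, 12 lists passed, the 5 added being mitochondrial ribosomal proteins and ecdysone response, Trithorax group, circadian clock and microRNA genes. Without replicate 3, 9 passed, with mitochondrial ribosomal proteins and ecdysone response, tRNA and microRNA genes added. The EGFR and Ras list passed with a 1000 bp window (11 of 15) and with 1 gene per peak. Peaks were found at 6 of 15 genes of the EGFR and Ras pathway, 6 of 17 of the Polycomb group, 5 of 13 of the Trithorax group, 9 of 31 cell cycle genes, 4 of 14 in the Notch pathway, 3 of 14 in the Wingless pathway, 2 of 14 in the Hedgehog and Dpp pathways, 3 of 11 of the Enhancer of split complex and 3 of 33 patterning transcription factors. The counts were 12 of 52 for translation factors, 9 of 35 for spliceosome and snRNP proteins, 6 of 48 for proteasome subunits, 14 of 84 for oxidative phosphorylation subunits, 5 of 25 for heat shock genes and 3 of 9 for circadian clock genes. They were 3 of 18 for neuronal genes, 3 of 18 for muscle genes, 2 of 12 for the piRNA pathway, 1 of 8 for ecdysteroid synthesis and 21 of 290 for tRNA genes. None of the 20 antimicrobial peptide, 14 fat body and haemocyte, 19 testis-specific and 32 snRNA genes had a promoter peak, and with adjusted p of 0.0974, 0.195, 0.0974 and 0.209 these lists did not pass either (Fisher's exact tests).

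**Figure D3:**
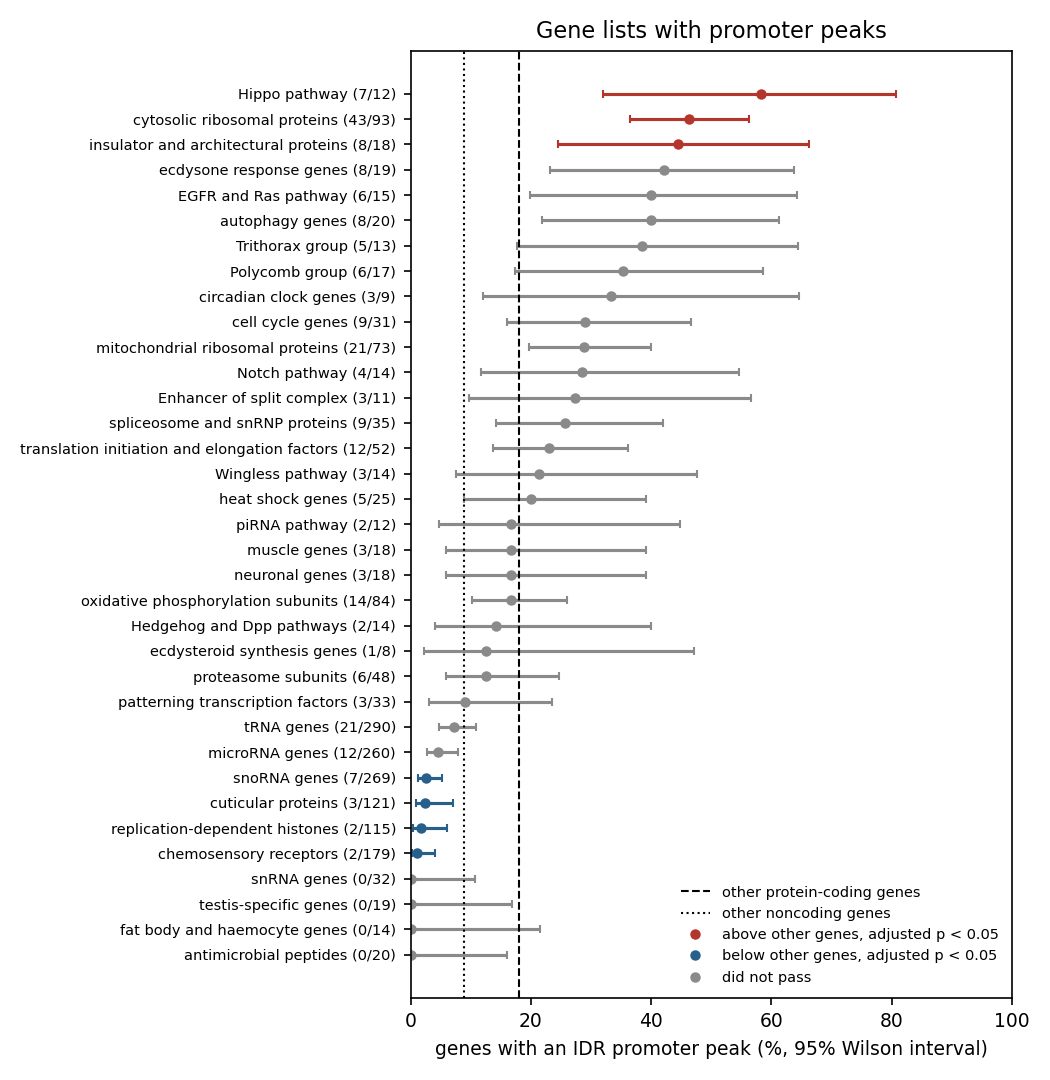
Share of the genes of each of the 35 lists with an IDR promoter peak, in percent, with 95% Wilson intervals and counts beside each name, and the share of other genes as vertical lines. The 3 lists in red lie above other genes and the 4 in blue below at an adjusted p under 0.05, and the 28 in grey did not pass.

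The tagged gene itself carried a peak. CG9948 (3L:6955991 to 6957440) was overlapped by 1 peak in each of the 4 lists. The IDR peak spans 3L:6955899 to 6956215, with its summit at 6956063 and rank 434 of 7637 by signal (1221). It ranked 586 of 30000 in replicate 1 and 420 of 30000 in replicate 3. A transgene adds copies of this locus to the genome, so this peak can hold reads from the transgene.

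IDR summits lay in AT-rich DNA with flanks below the genome mean. Within 50 bp of the summit the mean A + T content was 69.8%, against 54.9% in windows centred 200 bp away, a difference of 14.9 percentage points (95% interval 14.7 to 15.2) with the summit higher in 6852 of 7637 peaks (89.7%). The genome mean is 57.8%. The difference was 12.5 points at promoter peaks, 15.3 in introns and 17.7 in intergenic DNA. This measurement was added after the motif counts had been seen.

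**Figure D4:**
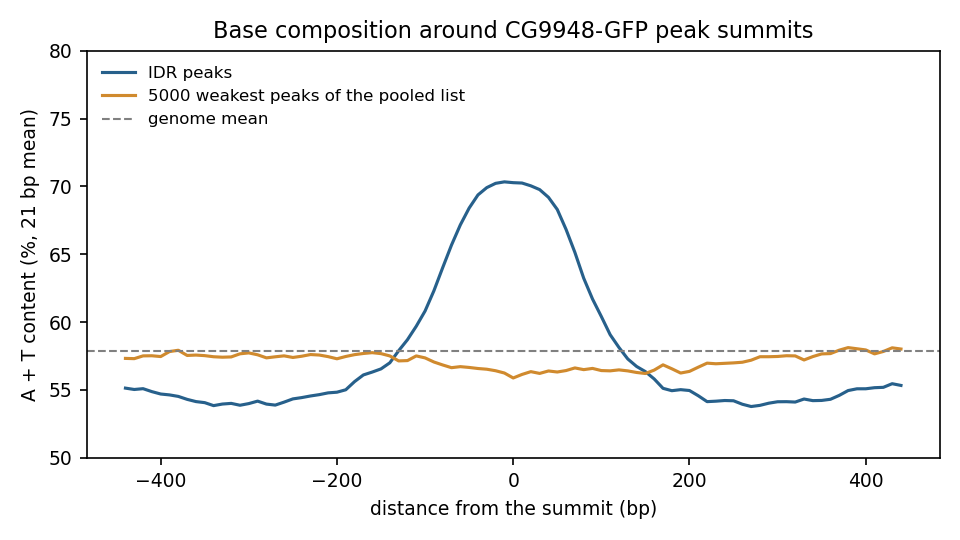
Mean A + T content in percent, averaged over 21 bp, by distance from the summit in bp, for IDR peaks (blue) and the 5000 weakest peaks of the pooled list (orange), with the genome mean of 57.8% dashed. IDR peaks average 69.8% within 50 bp of the summit, and the weakest peaks 56.3%.

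Motifs more frequent at summits than in flanks were mostly AT-rich. Of 23 known motifs, 6 were more frequent within 50 bp of the summit and 10 less frequent, and 7 did not pass (two-sided exact McNemar tests with Benjamini-Hochberg adjustment). The most frequent was the forkhead motif RTAAAYA, in 25.3% of summit windows against 13.6% of flanks (adjusted p = 1.98e-74), followed by the homeodomain site TAATTA (12.3% against 4.86%, adjusted p = 2.38e-61), the TATA box (11.2% against 3.69%, adjusted p = 1.09e-69, all exact tests), Ohler motif 6 (5.13% against 2.29%), STAT (3.64% against 2.45%) and Su(Hw) (0.799% against 0.406%). Less frequent at the summit were the E-box CAGCTG (1.74% against 6.17%), the GAGA factor (0.956% against 4.35%) and CACGTG (0.380% against 1.47%), and also Runt, Ohler motif 7, the DPE-like element, Grainy head, AP-1, the Initiator and the M1BP motif. Leaving out a replicate ended the calls of M1BP (log2 ratio -1.07, and -0.50 without replicate 1 and -1.03 without replicate 3), AP-1 (-0.71, and -0.33 without replicate 1) and the Initiator (-0.22, and -0.088 without replicate 3), and raised Su(Hw) from 0.97 to 1.85 without replicate 3. With flanks 400 bp away, M1BP, AP-1 and the Initiator did not pass either. In peaks outside promoters the direction of M1BP turned, with 11 summit windows and 0 flank windows holding it. Several of these calls turned against dinucleotide-shuffled summit windows: the homeodomain site was less frequent at summits than in them (15.8%, adjusted p = 4.95e-09), the GAGA factor (0.419%, adjusted p = 0.000292) and CAGCTG (1.10%, adjusted p = 0.00368) more frequent, and the TATA box and STAT did not differ detectably (10.7%, adjusted p = 0.466, and 3.18%, adjusted p = 0.222, all exact tests). Of 8192 7-mers, 1759 were more and 4009 less frequent at the summit (exact tests). The sequences of the 7-mers with the smallest p are not used here. Against genomic windows with the same A + T content at centre and flanks, a comparison added after the data were seen, only 22 7-mers were more and 17 less frequent. In the same comparison the forkhead motif was less frequent at summits (25.3% against 27.8%, adjusted p = 0.00412, exact test), whereas it was more frequent than in dinucleotide-shuffled windows (22.1%, adjusted p = 1.59e-05, exact test), so its direction depends on the comparison. Against the matched windows M1BP (0.196% against 0.0262%, only 15 and 2 windows) and Ohler motif 7 (2.78% against 1.70%) were more frequent, opposite to the comparison with flanks. The matched windows lay away from pooled peaks and were matched on A + T content only, not on promoter share. Differences from them in motifs and 7-mers can therefore also come from where the windows lie, which was not tested. All other motifs called against flanks did not pass against matched windows, among them Ohler motif 6 (5.03%), STAT (3.86%), Su(Hw) (0.629%), the GAGA factor (0.681%) and CAGCTG (1.52%).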

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

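Chosen after the data were seen were the tests with 1 summit per group of overlapping peaks, with composition-matched windows, with shuffled windows for 7-mers and with all annotated noncoding genes, and those of A + T content. Of 361 values recomputed, 283 kept their direction and side of the threshold (or, for counts, stayed within 1.5 times), 44 no longer passed, 2 newly passed, 8 counts moved and 24 changed direction. All 6 values for replicate overlap, 7 for the promoter share, 4 for promoter share by strength, 6 for divergent promoters, 6 for summit position and 7 for A + T content kept both, although the A + T difference fell from 14.9 to 2.52 points in pooled peaks below the IDR threshold. The noncoding exon excess (log2) was 0.25 with a 1000 bp window, 0.47 in the strongest 3818 peaks and between 0.38 and 0.54 when either replicate was left out. The X odds ratio was 0.937 with a 250 bp window, 1.14 with 1000 bp, 0.946 in the strongest peaks and from 0.963 to 1.17 when either replicate was left out. The ribosomal protein odds ratio in the strongest peaks was 0.393. Without replicate 1, 7 lists lay above other genes, and 3 without replicate 3. With all annotated noncoding genes, the set first used, 4 lists lay above and 5 below. Coding exons held 0 of the strongest 3818 summits (a limit of 3 counts is 0.0786%) against 13.6% of shifted ones, so no ratio was formed. Against shuffled windows, 2 motifs were less frequent at summits, 329 7-mers more and 318 less. Motif log2 ratios that turned there were 2.63 for M1BP, 0.45 for Ohler motif 7, 0.66 for CAGCTG, 0.20 for the Initiator, 1.18 for GAGA factor, -0.36 for homeodomain, 0.53 for Grainy head and 0.045 for AP-1. Of these, Grainy head (adjusted p = 0.243, exact McNemar test) and AP-1 (65 against 63 windows) did not pass. Against composition-matched windows, 2 motifs were more and 1 less frequent, and 22 7-mers more and 17 less. The ratios that turned were 2.63 for M1BP, 0.70 for Ohler motif 7, 0.20 for CAGCTG, -0.14 for the TATA box, 0.49 for GAGA factor, -0.13 for homeodomain, 0.22 for Grainy head, 0.69 for AP-1, -0.085 for STAT and -0.14 for forkhead. Of these, only M1BP, Ohler motif 7 and forkhead passed. M1BP was also at 0.096 with flanks 400 bp away and at 4.52 outside promoters, a value set by the 0.5 added, since 11 summit windows and 0 flank windows held it (at least 3.67-fold at a limit of 3 counts). Both of its ratios of 2.63 rest on 15 against 2 windows (7.5-fold, 95% interval 1.74 to 67.6). Both kinds of window take base content out of the comparison by construction, but the matched windows were not matched on promoter share. For the other changes the cause was not tested. No paired analysis was possible because there is a single group.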

Other observations

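The test of the weakest pooled peaks was chosen only after its result was seen, while the composition-matched windows and the CACTG core were chosen after other results had been seen, and the test of that core at equal composition after the one without it. The low number of peaks on chromosome 4 was also known before its matched share was computed, and its share per replicate was added after that.

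The AT-rich block at IDR summits was weighed against technical causes. The 5000 weakest pooled peaks had summits -0.697 percentage points from their flanks (95% interval -1.01 to -0.387) and all pooled peaks below the IDR threshold 2.52 points above them, which argues against a bias of the full 14.9 points in every called peak. The strongest of 5 groups of IDR peaks by signal had 18.4 points. A smaller bias shared by all peaks stays open. So does a bias of any size that itself raises the signal of AT-rich DNA, since the peaks were compared by signal. If loss of AT-rich DNA from the control were the sole cause, windows of equal composition would be covered alike wherever they lie, but promoter windows lay in IDR peaks more often than intergenic ones (odds ratio 2.18, 1.90 to 2.49), and a partial effect of the control stays open. The annotated CG9948 protein of 218 residues holds 0 AT-hook cores, so a hook of that form is not a candidate explanation. Other ways of binding AT-rich DNA, indirect binding and open chromatin were not tested, and neither was a biological explanation, since there is a single group.

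For the uneven placement of summits, composition-matched windows had a promoter share of 14.1% against 29.9% of IDR summits, so A + T content does not account for the promoter excess, which pooled peaks below the IDR threshold, with their smaller A + T difference, also showed (25.1%, 24.5 to 25.7). The coding exon share was 2.55% in matched windows and 4.17% in those weaker peaks, between the 13.7% of shifted summits and the 0.0655% of IDR summits. The deficit was 209-fold against shifted summits and still 39.0-fold against matched windows, so composition may account for part of it only. Introns held 46.5% of matched windows and 46.7% of IDR summits, so the intron excess over shifted summits is not seen at equal composition, while the 5′ UTR deficit shrank (0.406% against 0.524%) and the 3′ UTR deficit grew from 8.24-fold to 12.6-fold. On chromosome 4, which has the highest A + T content (64.8%), matched windows had a share of 1.03% against 0.170% of IDR peaks. Among the 7637 strongest peaks of replicates 1 and 3 the share was 0.0524% and 0.223% against 0.903% and 0.938% of their own matched windows, but among all 30000 it was 0.0233% and 0.653%, so the size of the deficit differs between replicates. Read placement was not measured for the matched windows either, so its part in all these shares was not tested.

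Genes with divergent neighbours had peaks more often also among genes of similar A + T contrast near the TSS (Mantel-Haenszel odds ratio 3.77, 3.44 to 4.13) and of similar TSS number (3.55, 3.24 to 3.90), against 3.64 without strata. Neither property is therefore likely to be the main cause. Peaks that a gene has through the promoter of its neighbour were not separated, and chromatin state and expression were not analysed here. The share of protein-coding genes with a promoter peak went from 6.64% in the tenth of lowest contrast to 30.7% in that of the highest.

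Of the 22 7-mers more frequent than in composition-matched windows, which were not matched on promoter share, 8 hold CACTG. This core was in 14.5% of summit windows against 9.76% of matched ones, an excess that follows from how the core was chosen and adds no support, and in 20.2% of flanks, which hold more G and C. A hypothesis that the core marks stronger binding was tested: of 5 groups of peaks by signal, 11.7% of the strongest and 17.7% of the weakest held it (odds ratio 0.613, 0.496 to 0.755, Fisher's exact test, p = 2.43e-06). Summits of the strongest group are more AT-rich (71.8% against 67.8%), and the windows matched to both groups held the core in 9.50% and 10.3% (odds ratio 0.910, 0.713 to 1.16). Within bins of summit A + T content the odds ratio of the peaks was 0.850 (0.682 to 1.06, Mantel-Haenszel), nearer to 1 than 0.613. A higher share in strong peaks is therefore argued against, while how far composition accounts for the lower share stays open.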
